A study of Rattus with 6 samples.

How the data were processed

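RNA sequencing was done on 6 libraries of cultured vascular smooth muscle cells, the contractile cells of the artery wall, taken from aorta as primary cultures per the labels. All 6 cultures were treated with angiotensin II (Ang II), a peptide hormone that constricts vessels and drives smooth muscle growth. Of these libraries, 3 carry the label si-NC (control siRNA, wild-type genotype label) and 3 carry the label si-CDCP1 (siRNA against CDCP1, knockdown genotype label). No culture without Ang II and no culture without siRNA was analysed here. Total RNA was column-purified and made into libraries with a kit that copies polyadenylated RNA by template switching, per the labels' protocols.

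The values are FPKM, fragments scaled to gene length and library size, as the authors deposited them in 1 table for the 6 libraries with a gene length, gene type and mouse Ensembl identifier for each gene, per the file headers. The genome build in the submitters' processing notes is mm10, a mouse build, while the organism label is rat. The aligner, the counting tool, its treatment of reads that match several places and its strand setting are not given in the sources used here. No reference genome was used here, so that coordinates are those of the deposited table on mm10. Of the 54012 genes in the table, 53801 carry a mouse Ensembl identifier and 211 have no name. The gene names of 11 genes had turned into calendar dates and were not matched to any list.

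Whole reads could be read back from the deposited FPKM. In each library every FPKM above 0, multiplied by the gene length in the table, was a whole multiple of 1 step (100.0% of values within 0.01 of a whole read). The reads in listed genes came to 19771638, 16050517 and 17598647 for si-NC replicates 1, 2 and 3 and to 17295710, 16275836 and 16230958 for si-CDCP1 replicates 1, 2 and 3. The library totals that the steps imply equalled median-of-ratios size factors, computed from the recovered reads of the 16824 genes with reads in all 6 libraries, times the geometric mean of the 6 read sums (largest difference 0.00021%). The deposited FPKM had thus already been scaled between libraries by the median ratio of genes rather than by the number of reads. As a result the listed reads were 98.4% of the implied total in each si-NC library, 99.9% in si-CDCP1 replicates 1 and 2 and 104% in si-CDCP1 replicate 3. A floor of 3 reads in a gene of 1 kb corresponded to between 0.149 and 0.192 FPKM. Intervals and floors from reads cover counting error only.

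The main comparison, si-CDCP1 against si-NC, used log2(FPKM + 1) and the 12080 genes with a mean of at least 1 FPKM over the 6 libraries (10490 of them protein coding). It was tested with limma 3.58.1 (R 4.3.3), a moderated test with an intensity trend, two-sided, with Benjamini-Hochberg (BH) adjustment and a threshold of 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. No pairing was used. Counts for a list are given over all genes and adjusted over the list alone. The 24 gene lists and 9 lists of markers of other cell types were tested as sets with limma's camera at a preset correlation of 0.01 between genes, where at least 5 members were tested, and again with an estimated correlation. Fry, a rotation test of whether the genes of a list move in 1 direction (directional) or at all (mixed), was run too. Cdcp1, which lies below the filter, was taken from the fit without it and compared by reads with an exact binomial 95% interval. The labels do not say that the replicates came from separate animals or isolations, so that p-values measure only the spread between these libraries, which may be technical. No pair of replicates was a duplicate, since the chi-square per degree of freedom between recovered reads was at least 2.98 in every pair.

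The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Cdcp1, the 12 largest rises and 12 largest falls past the adjusted threshold or, where fewer than 5 genes pass in a direction, the 12 with the smallest p in that direction, with values only. It further takes up to 4 members of each list that pass, or the 2 with the smallest p where none passes, and in any case a fixed set of genes that includes Pink1, Bnip3, Map1lc3b, Sqstm1, Acta2, Myh11, Src and Agtr1a. Some genes that the rule names are not reported here. Genes named outside this rule were chosen after their values were seen. Other settings fixed at that point were other pseudocounts (0.1 and 0.01 FPKM), filters, scalings (median log ratio, quantile, equal sums), no trend, library weights, the replicate number as a block, protein-coding genes, stricter thresholds, an estimated correlation and each library left out in turn. Added after the data had been seen were limma voom on the recovered reads (genes with at least 10 reads in 3 libraries) and removal of each library's trend with gene length (lowess, span 0.3), each with and without si-CDCP1 replicate 3.

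The main test was checked on counts simulated for the same genes and library sizes, with 200 genes changed by known folds. With each library's own dispersion, 92.6% of 95 genes changed by a factor of 2 and 79.6% of 98 genes changed by a factor of 1.5 were recovered at the adjusted threshold, with 10 false calls among 176. All genes of a library were drawn with 1 shared dispersion and independently of each other. Real genes differ in spread and move together, so these shares need not hold for the real libraries. Figures were drawn with matplotlib 3.10.9.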

Results

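The transcriptome of cultures labelled as aortic smooth muscle cells, under Ang II, was compared between si-CDCP1 and si-NC. The si-CDCP1 cultures (3 libraries) were given an siRNA against CDCP1 and the si-NC cultures (3 libraries) a control siRNA. Per the series title, the study concerns CDCP1 in carotid artery stenosis and mitochondrial autophagy. CDCP1 is a transmembrane glycoprotein that is phosphorylated by Src family kinases. The libraries held between 16050517 and 19771638 reads in listed genes, and 26005 genes had a value above 0 in at least 1 library. The samples are labelled as rat, whereas the deposited values are given for mouse genes on the mouse build mm10, so gene names below are mouse names. Whether the cells were mouse, or rat reads were aligned to the mouse build, was not settled here. A value near 0 therefore need not mean that a transcript was absent.

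Cdcp1, the siRNA target, was close to undetected in both groups. The gene (ENSMUSG00000035498, protein coding, mm10 chromosome 9, 123170824 to 123216038, minus strand) had a mean of 0.0137 ± 0.00501 FPKM in si-NC and 0.0151 ± 0.0262 FPKM in si-CDCP1 (SD, n = 3 each). These values stand for 2, 2 and 1 reads in the si-NC libraries and 0, 5 and 0 reads in the si-CDCP1 libraries. The ratio of read shares over the libraries of each group, si-CDCP1 over si-NC, was 1.07, with an exact binomial 95% interval from 0.247 to 4.66. An exact two-sided permutation test gave p = 1, where 3 libraries against 3 can reach no less than 0.1. A floor of 3 reads corresponds to between 0.0221 and 0.0284 FPKM for this gene, and the labels could not be checked by a knockdown of Cdcp1. The floor lies far below the filter of 1 FPKM, so the size of the libraries does not explain a value near 0. Little Cdcp1 transcript in these cultures, si-NC included, or a mismatch of species and build could each leave the gene near 0. These 2 were not told apart here.

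The smallest p-values of the comparison belonged to Oas2 and Irf7, both with lower values in si-CDCP1. Oas2, a 2'-5'-oligoadenylate synthetase that senses double-stranded RNA, averaged 28.6 ± 1.67 FPKM in si-NC and 16.4 ± 0.659 FPKM in si-CDCP1 (SD, n = 3 each), a log2 difference of -0.76 (SE 0.060). Irf7, a transcription factor of the type I interferon response, averaged 73.6 ± 2.76 FPKM against 52.4 ± 0.578 FPKM, a log2 difference of -0.48 (SE 0.047). Oas3, the sensor Zbp1 and the interferon-induced Ifi27l2a had log2 differences of -0.63 (SE 0.078), -0.42 (SE 0.054) and -0.72 (SE 0.11). Each of these 5 genes was lower in all 3 si-CDCP1 libraries than in any si-NC library, which the rule for named genes required. Chance gives such a separation of the groups, in either direction, to 10% of genes. None reached the threshold in the limma moderated test over all genes, where the BH-adjusted p was 0.0505 for Oas2 and 0.0815 for Irf7.

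The smallest p-values among genes with higher values in si-CDCP1 belonged to Ndufc1 and Cycs. Ndufc1, a subunit of respiratory complex I, averaged 10.5 ± 0.342 FPKM in si-NC and 15.3 ± 0.478 FPKM in si-CDCP1 (SD, n = 3 each), a log2 difference of 0.49 (SE 0.052). Cycs, which encodes cytochrome c, averaged 33.6 ± 0.174 FPKM against 41.5 ± 0.353 FPKM, and the collagenase gene Mmp13 15.8 ± 2.97 FPKM against 26.2 ± 1.02 FPKM. Enpp2, which encodes the lysophosphatidic acid-producing enzyme autotaxin, had a log2 difference of 0.64 (SE 0.099), and Atp6v0b, a subunit of the proton pump of lysosomes, one of 0.36 (SE 0.054). The log2 differences of Mnt, Pcbd2, Tmem256, Vat1, Mgat2, Fkbp11 and Rrs1 were 0.34, 0.36, 0.33, 0.32, 0.30, 0.29 and 0.25. On the lower side, the desmosome-linked Ppl had a log2 difference of -0.64 (SE 0.086), the matrix glycoprotein gene Thbs1 -0.42 (SE 0.074) and the aggrecanase gene Adamts5 -0.40 (SE 0.075). Aox1, Cdc7 and Ccnl2 followed with log2 differences of -0.37, -0.35 and -0.29. The microRNA gene Mir3079 averaged 4.12 ± 0.565 FPKM against 0.465 ± 0.403 FPKM, on 20 reads in si-NC and 2 reads in si-CDCP1.

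**Figure D1:**
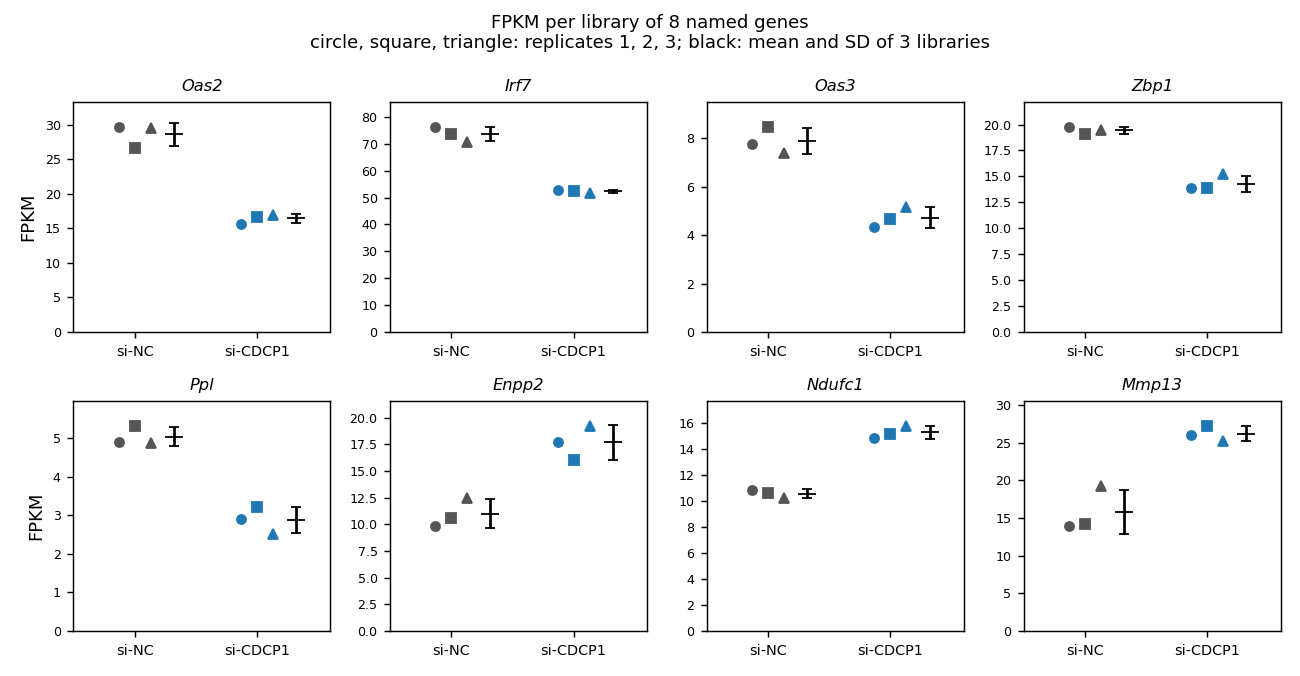
FPKM of Oas2, Irf7, Oas3, Zbp1, Ppl, Enpp2, Ndufc1 and Mmp13 in each library (vertical axes, FPKM from 0), grey for si-NC and blue for si-CDCP1, with circles, squares and triangles for replicates 1, 2 and 3 and the mean and SD of 3 libraries in black. The 3 libraries of a group lie apart from the 3 of the other group for each of the 8 genes, as the rule for named genes required. Means go from 28.6 FPKM in si-NC to 16.4 FPKM in si-CDCP1 for Oas2 and from 10.5 to 15.3 FPKM for Ndufc1.

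Over all 12080 genes tested, limma called 0 genes at a BH-adjusted p of 0.05, while 1722 genes had an unadjusted p under 0.05, 1080 of them higher and 642 lower in si-CDCP1. With every library rescaled to the same FPKM sum, the split was 544 higher and 1299 lower. Limma voom on the recovered reads, added after the data had been seen, called 7 of 14365 genes: Oas2, Irf7, Oas3, Ppl, Zbp1 and a gene without a name fell, and Enpp2 rose. In that voom test the BH-adjusted p was 0.00112 for Oas2, 0.00844 for Irf7 and 0.0457 for Enpp2; over the 21 settings tried the adjusted p ranged from 9.33e-07 to 0.294 for Oas2, from 8.36e-06 to 0.421 for Irf7 and from 0.000281 to 0.645 for Enpp2. The calls depended on si-CDCP1 replicate 3, a library that stood apart from the other 5. Without it, limma on log2 FPKM still called 0 genes, with 2002 at an unadjusted p under 0.05, and voom called 396 genes (212 higher, 184 lower). Limma called 1 gene without si-NC replicate 2 (n-R5s15) and 1 without si-NC replicate 3 (Mir7059). With all 6 libraries and limma's library weights, 865 genes were called (558 higher, 307 lower), and 275 of the 396 genes were among these, each in the same direction. Library weights are estimated from the same data and count a more variable library for less. The weighted fit may thus also discount si-CDCP1 replicate 3, and the weights were not reported here. Both results rest on the same libraries, so this overlap is not independent support.

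In the si-CDCP1 replicate 3 library 20 of 24 interferon response genes, 17 of 19 cholesterol synthesis genes and 11 of 16 inflammatory genes were above every other library, against 4107 of all 12080 tested genes. Its Pearson correlation with the other libraries on the log2 scale lay between 0.979 and 0.983, against 0.988 to 0.991 among the other 5. In it 57 protein-coding genes lay more than 1.5-fold above, and 25 more than 1.5-fold below, every other library; no other library had more than 3 on either side. Cxcl10, an interferon-induced chemokine, was at 93.5 FPKM there and at 35.0 ± 2.23 FPKM in the other 5 libraries (SD, n = 5). Ifit1, an interferon-induced inhibitor of viral translation, was at 246 FPKM against 119 ± 6.12 FPKM, Ccl7 at 195 FPKM against 70.6 ± 11.8 FPKM, and the sterol sensor gene Insig1 at 87.3 FPKM against 41.8 ± 4.88 FPKM. Cxcl10, Ifit1, Ccl7 and the other genes in the plot of interferon and chemokine genes were chosen after their values were seen.

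**Figure D2:**
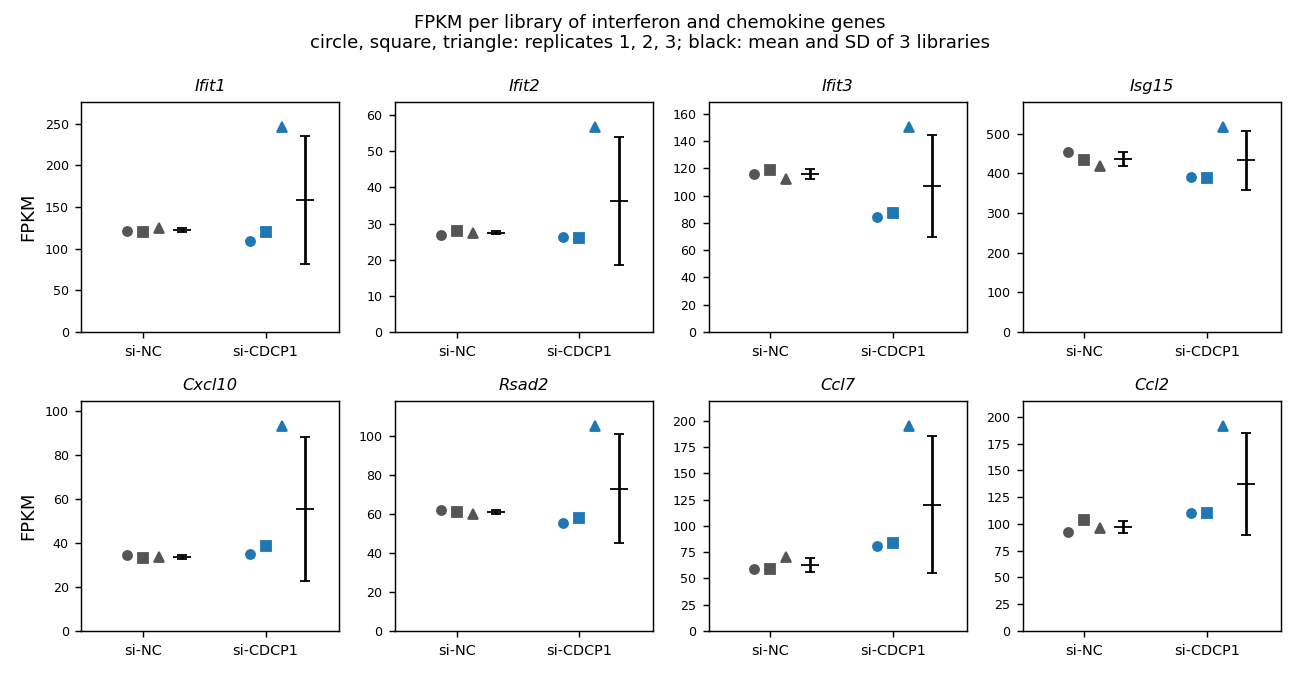
FPKM of Ifit1, Ifit2, Ifit3, Isg15, Cxcl10, Rsad2, Ccl7 and Ccl2 in each library (vertical axes, FPKM from 0), grey for si-NC and blue for si-CDCP1, with circles, squares and triangles for replicates 1, 2 and 3 and the mean and SD of 3 libraries in black. For each of the 8 genes the si-CDCP1 replicate 3 library (blue triangle) is the highest, at 246 FPKM for Ifit1 and 93.5 FPKM for Cxcl10, while for Ifit3 the si-CDCP1 replicates 1 and 2 are at 84.2 and 87.3 FPKM, below the si-NC libraries at 112 to 119 FPKM.

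Of the interferon response list (24 tested members), 0 genes passed over all genes and 1, Irf7, fell when adjusted over the list alone. The list had 13 members with positive and 11 with negative log2 differences and a median of 0.01, while camera gave the direction down (BH-adjusted p = 0.445, and adjusted p = 0.947 with an estimated correlation). Oasl2, another member of the oligoadenylate synthetase family, averaged 66.8 ± 3.03 FPKM in si-NC and 54.5 ± 10.5 FPKM in si-CDCP1 (SD, n = 3 each). Without si-CDCP1 replicate 3 the median was -0.18 and the list fell as a set in camera (BH-adjusted p = 4.66e-13), a call lost with an estimated correlation (adjusted p = 0.364). It also fell with library weights on all 6 libraries (adjusted p = 1.87e-05); over the other settings at the preset correlation the adjusted p ranged from 1.38e-17 to 0.911, and camera gave the direction up without si-CDCP1 replicate 1 or 2. In voom on those 5 libraries, 12 of 25 tested members fell and 0 rose over all genes, among them Ifit3, Isg15, Oas1a and Usp18.

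The lysosome list rose as a set in camera at the preset correlation (BH-adjusted p = 3.62e-07), a call lost with an estimated correlation (adjusted p = 0.817). Of its 24 tested members, 22 had positive log2 differences, with a median of 0.17, and 8 rose when adjusted over the list alone (among them Lamp1, Ctsa, Ctsl, Hexa, Gla, Cd63 and Grn), 0 over all genes. Cd63, a membrane protein of late endosomes and lysosomes, averaged 168 ± 5.57 FPKM in si-NC and 204 ± 8.43 FPKM in si-CDCP1, and Ctsl, a lysosomal protease, 72.6 ± 1.96 FPKM against 83.6 ± 0.806 FPKM (SD, n = 3 each). In si-CDCP1 replicate 3, 15 of the 24 members were above every other library, and without that library the median was 0.13.

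Nuclear genes of oxidative phosphorylation, the unfolded protein and integrated stress response, and cholesterol synthesis were the other lists that rose as sets at the preset correlation. Camera gave BH-adjusted p-values of 0.000452, 0.000386 and 0.000309 for the 3 lists, and each call was lost with an estimated correlation (adjusted p = 0.817 for each). Of 32 oxidative phosphorylation genes, 25 had positive log2 differences (median 0.08), and Cycs alone rose when adjusted over the list. Cox5a, a subunit of cytochrome c oxidase, averaged 22.0 ± 0.404 FPKM against 25.5 ± 0.767 FPKM (SD, n = 3 each). Of 20 stress response genes, 18 had positive log2 differences (median 0.10), and Ddit3, a transcription factor of the stress response, rose when adjusted over the list alone, from 94.2 ± 1.78 to 114.9 ± 7.87 FPKM, while the chaperone gene Calr averaged 289.6 ± 4.86 and 318.5 ± 0.251 FPKM. All 19 cholesterol synthesis genes had positive log2 differences (median 0.20), and 0 passed when adjusted over the list alone. Insig1 averaged 38.2 ± 0.570 against 60.5 ± 23.2 FPKM, a log2 difference of 0.59 that went to 0.29 without si-CDCP1 replicate 3. The oxidative phosphorylation call was also lost without si-CDCP1 replicate 1 (adjusted p = 0.0669), and it and the stress response call were lost with quantile normalisation (adjusted p = 0.521 and 0.569). Deviations in si-CDCP1 replicate 1 had a rank correlation of -0.38 with gene length. With each library's length trend removed, both calls held at weaker camera adjusted p-values of 0.00718 and 0.00402. Members above every other library in si-CDCP1 replicate 3 numbered 11 of 32, 12 of 20 and 17 of 19, and without that library the medians were 0.11, 0.10 and 0.11.

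**Figure D3:**
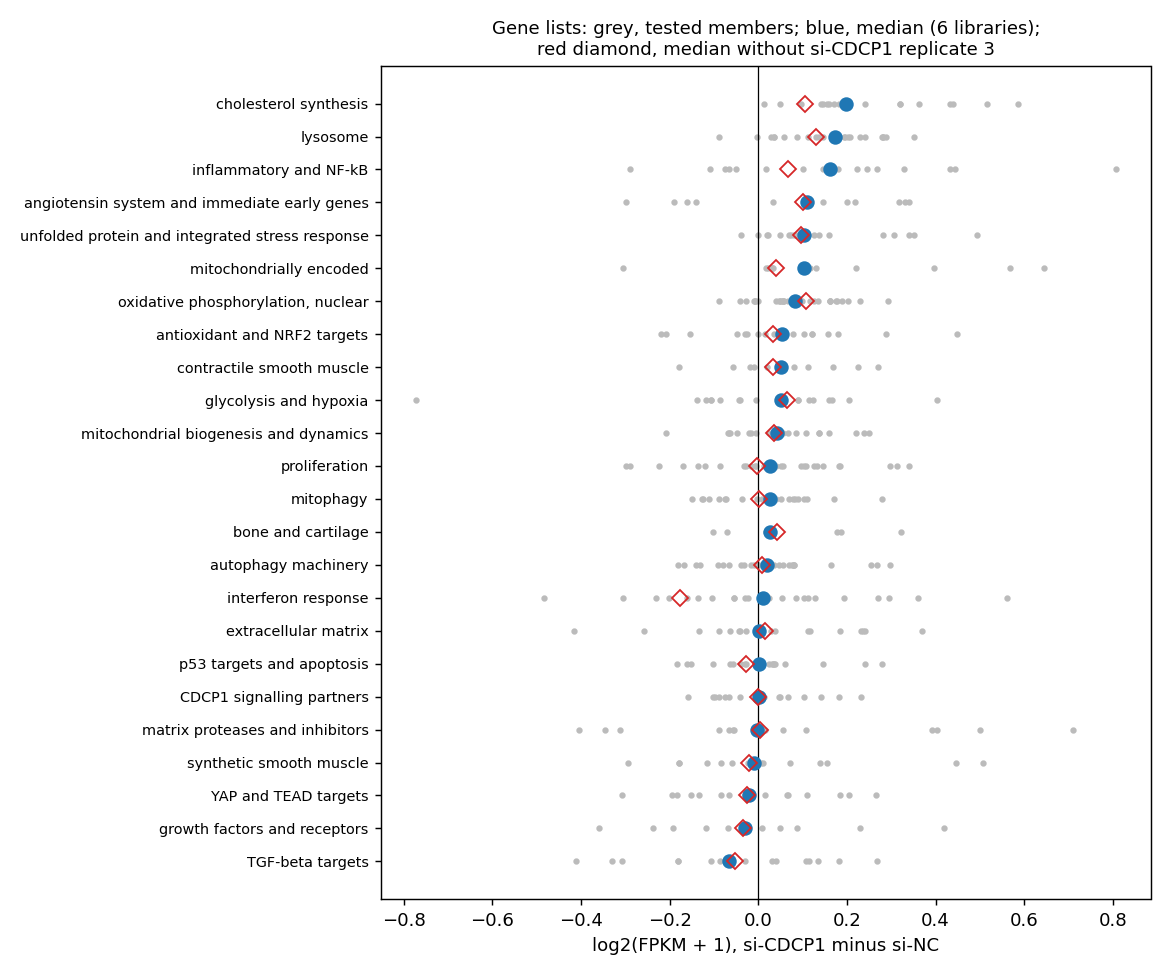
Log2(FPKM + 1) difference, si-CDCP1 minus si-NC (horizontal axis), for the tested members of 24 gene lists (grey points), with the median over 6 libraries (blue circle) and the median without si-CDCP1 replicate 3 (red diamond). The cholesterol synthesis and lysosome medians are 0.20 and 0.17 with all libraries and 0.11 and 0.13 without that library, and the interferon response median is 0.01 and -0.18.

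Mitophagy, the removal of damaged mitochondria by autophagy that the series title names, was covered by 21 tested genes, of which 0 passed over all genes or over the list alone. Sqstm1, the cargo receptor p62, averaged 468 ± 5.73 FPKM in si-NC and 569.7 ± 47.5 FPKM in si-CDCP1, and Pgam5, a mitochondrial phosphatase, 14.7 ± 0.336 against 16.7 ± 0.566 FPKM (SD, n = 3 each). Pink1, the kinase that marks damaged mitochondria, averaged 12.7 ± 0.584 against 12.03 ± 2.20 FPKM, and the mitophagy receptor gene Bnip3 6.45 ± 0.206 against 5.76 ± 0.946 FPKM. Among 28 autophagy genes 0 passed in either count: Map1lc3b, which encodes LC3B, averaged 34.0 ± 0.878 against 33.6 ± 2.18 FPKM, Gabarapl1 67.3 ± 0.715 against 81.4 ± 6.17 FPKM and Gabarap 102.8 ± 3.67 against 123.3 ± 13.0 FPKM. Camera gave BH-adjusted p-values of 0.896 for mitophagy and 0.907 for autophagy. The log2 differences of Pink1, Bnip3 and Map1lc3b were -0.09 (SE 0.12), -0.15 (SE 0.11) and -0.02 (SE 0.059); without si-CDCP1 replicate 3 they were 0.06, -0.03 and 0.04.

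Of the 13 mitochondrially encoded genes, 12 had positive log2 differences (median 0.10), 0 passed in either count, and camera gave a BH-adjusted p of 0.276. In si-CDCP1 replicate 3, 8 of the 13 were above every other library, and without that library the median was 0.04. The mt-Cytb gene averaged 2069 ± 43.9 against 2417 ± 249.7 FPKM, and mt-Atp8 2.22 ± 0.619 against 3.95 ± 1.87 FPKM (SD, n = 3 each). Without si-CDCP1 replicate 3 the log2 difference of mt-Cytb went from 0.22 to 0.14 and that of mt-Atp8 from 0.57 to 0.29. Of the 6 genes from mt-Co2 to mt-Nd4l, all but mt-Atp8 match in length a row of pseudogenes in reversed order on mm10 chromosome 1 with which they could share reads. The values of these 5 are therefore uncertain. That of mt-Atp8, which lies between mt-Co2 and mt-Atp6, is uncertain as well and rests on 25 reads in si-NC and 39 in si-CDCP1. Of 23 genes of mitochondrial biogenesis and dynamics 0 passed in either count (camera adjusted p = 0.445), with Nrf1 at 5.75 ± 0.0915 against 7.05 ± 0.644 FPKM and the mitochondrial polymerase gene Polg at 7.51 ± 0.399 against 6.38 ± 0.546 FPKM. Of 20 antioxidant genes Gpx4, which reduces lipid peroxides, rose when adjusted over the list alone, from 159.8 ± 5.96 to 195 ± 6.91 FPKM, and Txn1 averaged 144 ± 6.42 against 164 ± 4.45 FPKM (camera adjusted p = 0.423).

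Of 22 smooth muscle genes of the contractile class, 10 had a mean of at least 1 FPKM. Others such as Tagln, Cnn1 and Myh11 were near 0 in both groups. These markers therefore do not bear out the smooth muscle label. A mismatch of species and build could leave single genes near 0. It did not do so for the whole class, since Acta2, Tpm1 and Vcl averaged 37.4, 61.7 and 20.3 FPKM in si-NC. Acta2, smooth muscle actin, averaged 37.4 ± 1.95 FPKM in si-NC and 46.8 ± 15.5 FPKM in si-CDCP1, Tagln 0.161 ± 0.0486 against 0.141 ± 0.0964 FPKM, and Myh11, smooth muscle myosin, 0.0130 ± 0.0122 against 0.0351 ± 0.0257 FPKM (SD, n = 3 each). Of 10 tested contractile genes 0 passed in either count, with Tpm1 at 61.7 ± 1.05 against 72.5 ± 7.57 FPKM and Vcl at 20.3 ± 0.515 against 17.8 ± 1.61 FPKM. Of 14 genes of the synthetic state 0 passed either, with Lgals3 at 70.7 ± 2.99 against 102.3 ± 22.5 FPKM and Klf4 at 59.0 ± 1.84 against 82.4 ± 21.7 FPKM. Without si-CDCP1 replicate 3 the log2 difference of Acta2 went from 0.27 to 0.02, that of Klf4 from 0.45 to 0.24 and that of Lgals3 from 0.51 to 0.33. Those of Tpm1 and Vcl went from 0.22 to 0.14 and from -0.18 to -0.12. Among markers of other cell types, Pecam1 and Cdh5 of endothelium, Ptprc of blood cells and Epcam of epithelium each had a mean under 0.1 FPKM in both groups. Fibroblast Pdgfra averaged 10.4 ± 0.361 against 8.69 ± 0.984 FPKM, and macrophage Cd68, at 1.27 ± 0.0462 against 0.822 ± 0.0936 FPKM, fell when adjusted over its list of 3 tested genes alone. The endothelial, fibroblast, pericyte, adipocyte, neural, epithelial, T cell and erythroid marker lists, of which 0 to 3 genes were tested, had 0 genes past the threshold in either count. Of the 3 tested adipocyte genes 2, Lpl and Fabp4, were higher at an unadjusted p under 0.05 (median of the 3 log2 differences 0.39, and 0.24 without si-CDCP1 replicate 3). No marker list had the 5 tested members that the set test needs.

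Extracellular matrix genes moved in both directions when adjusted over the list alone: of 20 tested, Lox rose and Loxl2 and Thbs1 fell, with Loxl2, a lysyl oxidase that cross-links collagen, at 13.1 ± 0.733 against 10.8 ± 0.431 FPKM (SD, n = 3 each). Of 16 matrix proteases and inhibitors, Mmp13 and Timp3 rose and Adamts5 fell in that count. Among 19 p53 and apoptosis genes Bax, a pore-forming apoptosis protein, rose in that count from 48.6 ± 0.70 to 59.3 ± 4.13 FPKM, with Bbc3 at 7.82 ± 0.277 against 9.43 ± 0.548 FPKM, and among 7 bone and cartilage genes Sox9 rose from 5.46 ± 0.448 to 7.07 ± 0.653 FPKM. Over all genes 0 members of these 4 lists passed, and the camera adjusted p was 0.907 for the first 3 lists and 0.740 for bone and cartilage, where Bmp4 averaged 17.8 ± 0.852 against 20.3 ± 2.62 FPKM. Without si-CDCP1 replicate 3 the log2 difference of Timp3 went from 0.50 to 0.33 and that of Bmp4 from 0.18 to 0.09. Median, mean and test differed in sign for matrix, proteases, p53 and synthetic smooth muscle genes, whose medians lay between -0.01 and 0.00.

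The remaining lists had 0 genes past the threshold in either count. Of 28 proliferation genes, the cyclin gene Ccne1 averaged 9.44 ± 0.183 against 11.99 ± 0.967 FPKM and Bub1b 27.4 ± 0.293 against 31.3 ± 1.85 FPKM (SD, n = 3 each). In the inflammatory list of 16 genes, the chemokine Cxcl1 averaged 27.5 ± 3.30 against 37.3 ± 3.35 FPKM and Relb 19.7 ± 1.05 against 25.2 ± 4.39 FPKM. That list rose as a set in voom on all 6 libraries, but not in voom without si-CDCP1 replicate 3 nor in the main test (camera adjusted p = 0.316, and 0.833 with an estimated correlation). Its median was 0.16, and 0.07 without that library. Of 15 genes of the angiotensin system and immediate early response, Myc averaged 78.7 ± 0.780 against 99.8 ± 13.3 FPKM and Egr1 24.96 ± 2.45 against 20.1 ± 1.99 FPKM, while the angiotensin receptor gene Agtr1a lay below the filter at 0.316 ± 0.124 and 0.296 ± 0.144 FPKM. Of 17 CDCP1 signalling partners, Src averaged 20.2 ± 0.533 against 19.2 ± 2.19 FPKM, Fyn 30.8 ± 0.912 against 36.4 ± 4.43 FPKM and Hif1a 55.1 ± 2.04 against 62.6 ± 3.22 FPKM. Of 17 TGF-beta targets, Pmepa1 averaged 6.93 ± 0.159 against 8.57 ± 0.745 FPKM and Smad3 33.5 ± 1.42 against 29.4 ± 1.36 FPKM, and of 17 YAP and TEAD targets, Ctgf averaged 11.2 ± 1.14 against 8.90 ± 1.19 FPKM and F3 5.40 ± 0.473 against 6.37 ± 0.412 FPKM. Glycolysis and hypoxia (19 genes) gave Pgk1 at 184 ± 7.35 against 212 ± 12.6 FPKM and Ndrg1 at 33.2 ± 0.646 against 44.9 ± 9.65 FPKM, and growth factors (12 genes) gave Erbb3 at 1.80 ± 0.0791 against 1.19 ± 0.254 FPKM. Without si-CDCP1 replicate 3 the log2 difference of Ndrg1 went from 0.40 to 0.24, that of Relb from 0.33 to 0.20, that of Fyn from 0.23 to 0.14 and that of Src from -0.08 to -0.02. The camera adjusted p-values of these 8 lists and of the contractile and synthetic lists lay between 0.316 and 0.998. Over all 24 lists, fry gave none a directional adjusted p below 0.124. Its mixed test, which counts movement in either direction, gave 5 lists an adjusted p under 0.05. These were oxidative phosphorylation (0.0297) and extracellular matrix, lysosome, antioxidant and p53 genes (0.0492 each).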

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

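Voom on recovered reads, removal of the gene length trend and the tests on other splits were set up after the results had been seen. Limma on log2 FPKM called 0 genes (1722 at an unadjusted p under 0.05). Counts stayed at 0 with pseudocounts of 0.1 and 0.01 FPKM, without the trend, at an adjusted p of 0.01 and with a log2 difference of at least 1. Planned settings that called genes were no filter (7), a mean of at least 5 FPKM (4), median scaling (1), quantile normalisation (2), equal FPKM sums (1), protein-coding genes alone (2) and library weights (865). The protein-coding and stricter filters test fewer genes; for the others the cause was not tested. Leaving out 1 library at a time gave 0 to 1 genes (n-R5s15 without si-NC replicate 2, Mir7059 without si-NC replicate 3). Chosen after seeing the data, voom called 7 genes (396 without si-CDCP1 replicate 3) and removal of the gene length trend 3 (13 without that library). The planned edgeR and DESeq2 tests on recovered reads were not run. Same-numbered libraries did not deviate together (correlations -0.020, 0.026 and 0.022), and with the replicate number as a block 1 gene, Tmem150a, was called and 4 lists.

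Of the lists, 4 were called under the planned pseudocounts, filters, median scaling, equal sums, no trend and block, 5 with library weights (the 4 and the interferon list, which fell), 2 under quantile normalisation, 0 with an estimated correlation, 3 to 5 with 1 library left out (3 without si-CDCP1 replicate 1, 5 without si-CDCP1 replicate 3), and, chosen after seeing the data, 5 in voom on all libraries (the 4 and the inflammatory list, which rose), 7 in voom without si-CDCP1 replicate 3, and 4 with the length trend removed (6 without that library). Of 10 splits of the libraries, too few for a share under 0.05, the real split gave 0 called genes (highest other 0, and 10 splits with as many), 1722 genes at an unadjusted p under 0.05 (highest other 468, 1 split with as many) and 4 lists (highest other 5, 6 splits with as many).

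The log2 difference of Cdcp1, 0.0017 as reported, was -0.0045 and -0.40 with pseudocounts of 0.1 and 0.01 FPKM, -0.0081 with median scaling and between -0.020 and 0.012 with 1 library left out; a mean of at least 5 FPKM leaves no value. Its 10 reads limit any statement. The sign turned for Pink1 (0.063 with library weights, 0.048 in voom and 0.026 without the length trend, both without si-CDCP1 replicate 3; -0.17 to 0.061 with 1 library left out), for Map1lc3b (0.024, 0.017 and 0.052 likewise; -0.050 to 0.036 with 1 library left out), for Bnip3 (0.0018 with library weights) and for Acta2 (-0.066 with library weights, -0.030 without the length trend and that library). For Pink1 each turned sign came with library weights or with si-CDCP1 replicate 3 left out. Pink1 was at 9.49 FPKM in that library and between 12.1 and 13.4 FPKM in the other 5. Why it was lower there, and the cause for the other genes, was not tested.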

Other observations

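The tests in this part were chosen after the result was seen, except the rescaling of si-CDCP1 replicate 3 and the removal of the gene length trend, which was added after the data had been seen but before its own result, while the scalings tried on the interferon genes are planned settings. Beyond the groups described above, voom on recovered reads without si-CDCP1 replicate 3 called further members of several lists over all 14365 genes. The matrix genes Sparc and Bgn fell, with Loxl2 and Thbs1, while Lox rose. Hspa5, the main chaperone of the endoplasmic reticulum, rose with Ddit3, Atf3 and Calr, and the heme-degrading enzyme gene Hmox1 and the ferritin gene Ftl1 rose with Gpx4. In the mitophagy list 1 of 21 members, Sqstm1, rose, and in the autophagy list 1 of 28, Gabarapl1. Of the lysosome list 6 of 24 rose (Lamp1, Ctsa, Ctsl, Hexa, Cd63 and Grn) and 0 fell.

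The lower Oas2, Irf7, Oas3, Zbp1 and Ifi27l2a in all 3 si-CDCP1 libraries may reflect a lower basal interferon tone in these cultures, a hypothesis found on these same data. The main set test did not call the interferon list (camera adjusted p = 0.445, median log2 difference 0.01, 13 of 24 members positive). Library weights did at the preset correlation (camera adjusted p = 1.87e-05, lower). With an estimated correlation camera gave adjusted p = 0.947 on all libraries and 0.364 without si-CDCP1 replicate 3, and weights were not tried with it. In si-CDCP1 replicate 3, 20 of 24 genes of the interferon list were highest. The authors' scaling is argued against as the cause of the lower values. Under each of 3 other scalings Zbp1 had the log2 difference nearest to 0 among the 5 genes. It was -0.43 with median scaling, which is close to the deposited scaling, -0.45 with quantile normalisation and -0.49 with equal sums. A gene length trend is argued against too, since after its removal the log2 difference nearest to 0 among the 5 genes was -0.44. Loss of Cdcp1 could not be tested and stays open, since the gene had 5 reads over the si-NC libraries and 5 over the si-CDCP1 libraries. The ratio of Cdcp1 read shares, 1.07 with an interval from 0.247 to 4.66, allowed a loss as well as a gain. The si-NC mean of 0.0137 FPKM left little measured transcript for the siRNA to lower, unless a mismatch of species and build hid it. A different response to the 2 siRNAs themselves stays open too, because siRNA and group are the same factor here.

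The si-CDCP1 replicate 3 library stood apart, and its number of reads is unlikely to be the cause: si-CDCP1 replicate 2, at 16275836 against 16230958 reads, had 5 protein-coding genes more than 1.5-fold outside the other libraries against 82 in replicate 3. Scaling is unlikely as well, since under 3 other scalings that library had at least 63 such genes while no other library had more than 7. In that library 17 of 19 cholesterol synthesis genes and 20 of 24 interferon genes were above all other libraries, against 4107 of all 12080 tested genes. Another state of that culture at harvest, such as a stronger response to transfection, could give this pattern, but with 1 library it cannot be told apart from a handling or labelling error.

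The mt-Co3 gene was at 243 FPKM in si-CDCP1 replicate 3 and at 48.3 ± 4.52 FPKM in the other 5 libraries (SD, n = 5). A rise of all mitochondrial transcripts is argued against, since among the 7 mitochondrial protein-coding genes outside the stretch from mt-Co2 to mt-Nd4l the highest log2 difference in that library was 0.33, against 2.31 for mt-Co3. Of the 6 genes of that stretch, 5 match in length, within 3 bases and in reverse order, pseudogenes on mm10 chromosome 1, such as Gm28437 (24613189 to 24613971) for mt-Co3. An exchange of reads with Gm28437 is argued against, since Gm28437 did not fall: it was at 39.6 FPKM in that library and between 28.5 and 42.7 FPKM in the other 5, a change of 4.89 FPKM from their mean, while mt-Co3 rose by 195 FPKM. A change in how many reads are lost because they match both places stays open. The other 4 genes with a copy had log2 differences in that library from -0.56 to 0.94 (median 0.045), which does not decide it. No biological explanation other than a rise of all mitochondrial transcripts was tested.

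Some values are given here without a comparison of the groups. Gapdh, a housekeeping gene with many processed pseudogenes, was at 30.1 FPKM in si-NC replicate 1 and between 2.91 and 6.08 FPKM in the other 5 libraries. It was a tested member of the glycolysis and hypoxia list, whose log2 differences had a median of 0.05 and a mean of 0.0025. The rank correlation of a library's deviation with gene length was -0.38 in si-CDCP1 replicate 1 and between -0.10 and 0.12 in the other 5. Although the organism label is rat, mt-Co1 was the gene with rank 2 of the table by mean FPKM, and the mouse histocompatibility genes H2-K1 and H2-D1 averaged 722 ± 61.5 and 463 ± 47.9 FPKM (SD, n = 6). Of 19816 named protein-coding mouse genes, 2657 had no rat symbol or synonym in the RefSeq table of the rat assembly GRCr8, and 8.88% of these had a mean of at least 1 FPKM, against 58.3% of the 17159 with one. These shares cannot decide the species, since genes without a rat symbol may be low in such cultures for other reasons.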
